A study of Mus musculus with 8 samples.

How the data were processed

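The series holds 8 RRBS libraries from sorted pyramidal neuron nuclei of mouse medial prefrontal cortex, 4 Control and 4 PFC DKO, grouped by their labels. Per the labels' protocols, frozen tissue punches were processed in batches for nuclei, stained with an antibody to SATB2, and sorted for GFP, SATB2 and DAPI. The labels give the Controls the same Cre and GFP vector, whereas the deposited names mark Control libraries with GFP and PFC DKO libraries with Cre; the labels were followed. No batch is given for a sample, so batch and genotype could not be separated. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, inspected with FastQC, mapped to mm10 with Bismark 0.19.1 and Bowtie2, and handled in methylKit 0.99.2; the notes give no order of steps. Whether duplicate reads were removed is not given in the sources used here.

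The deposited calls come as a CpG and a CH file per library, 16 in all, with a position, a strand, the coverage and the methylated fraction of each cytosine, per the file headers. In 15 of the 16 files the header has 6 names and each line 5 cells, and the columns were read by their content. The deposited coverage, a signal of read depth per cytosine, is a whole number, and 1 of the CpG files also gives deposited counts of methylated and unmethylated reads. The deposited fraction runs from 0 to 1 and is printed here as a percentage. Methylated read counts were taken as coverage times fraction, rounded. The authors' deposited table of differences gives, per the file headers, a pooled methylation difference, a p-value and a q-value for each site. A site here is the cytosine of 1 strand.

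Positions were matched to RefSeq genes of the GRCm38.p6 assembly, which has mm10 coordinates, on chromosomes 1 to 19 and X (21631 protein-coding and 12697 long non-coding RNA genes). The gene table used here has no strand, exons or sequence. A promoter window could therefore not be placed, and the CpG-rich gene end was used in its place: 1000 bp outside to 500 bp inside whichever end held more CpG sites with 10 reads in at least 4 libraries. The gene body was the rest of the gene. The CpG-rich end had a median level of 1.79% over 8250 genes, and the other end 31.0% over 528. Exon and intron classes and the CA, CC and CT contexts, which need an exon table or a genome, were not analysed here. In their place CH sites were split by whether the next listed position showed that a C follows.

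The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where stated. Sites needed 10 reads in each of the 8 libraries. Library means, features and gene lists were compared by a two-sided exact permutation test over all 70 assignments of 4 of 8 libraries. The smallest p it can give is 0.0286, for 1 library left out also 0.0286, and for 2 left out 0.0667. Intervals (95%) invert that test. CpG sites, 1 kb tiles (at least 3 sites), CpG-rich gene ends (3 sites), gene bodies at CpG (5 sites) and at CH (50 sites) were tested with a quasi-binomial logistic model on methylated and unmethylated read counts. Its dispersion was moderated with squeezeVar of limma 3.58.1 and kept at 1 or above, followed by an F test and Benjamini-Hochberg adjustment at 0.05. A group at 0 or 100% in every library added no residual degrees of freedom. This adjustment was brought in after the first output had been seen, and without it the counts of calls were equal. Bisulfite PCR reads are not independent molecules, so depth alone overstates precision. The effective number of molecules per site, from the spread between libraries, was 1.59 to 3.65, lowest in PFC DKO replicates 3 and 1.

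The wider site set was added after the data were seen. It takes sites with 10 reads in at least 2 libraries of each group, centres each site on the mean of its 2 group means, averages over sites in a feature, and tests features measured in at least 3 libraries per group (20 CH sites) with limma. Site-centred values of a feature can fall below 0 or pass 100%. The values at Dnmt1 and Dnmt3a are of this kind.

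The 15 lists (429 members, 427 found in the annotation) were the DNA methylation machinery; imprinted genes; germline genes; glutamate receptors; postsynaptic scaffold and plasticity genes; GABA receptors; monoamine, opioid and cannabinoid receptors; feeding peptides, hormones and their receptors; activity-dependent genes; markers of pyramidal neurons, interneurons, astrocytes, the oligodendrocyte lineage, and microglia and endothelium; and clustered protocadherins. A list needed 3 measured members. Genes were named by rule: Dnmt1 and Dnmt3a; per feature type the 8 largest differences past the threshold in each direction, or the 3 smallest p where fewer than 3 passed; up to 4 members per list with the smallest p; and the 5 largest rises and falls of the authors' deposited table measured in all 8 libraries. Predicted genes, pseudogenes and small RNAs were counted and not named. List members named for gene body CpG fall outside that rule and were chosen after their values were seen, as were regions called only under an alternative.

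The alternatives were a minimum of 20 reads, the most covered sites left out, each library left out in turn, the replicate number as a block, unmoderated dispersion, edgeR 4.0.16 on the counts, Fisher's exact test on pooled reads, a stricter threshold, other tile sizes, windows and site minimums, every site of each library, and the mitochondrial CH level subtracted. Those added after the data were seen were the wider site set, the split by a following C, leaving out X, sites over 1000 reads or the most covered window, the fixed degrees of freedom, the mitochondrial level at shared sites, and leaving out PFC DKO replicates 1 and 3 together. The site test was tested on simulated data: of 200 changed sites among 19209, it recovered 0% with 3 molecules per library, 3% with 10 and 82.5% with 30. On the wider set limma recovered, for shifts of 20 and 40 points, 46% and 60% of changed tiles, 64% and 89% of gene ends, and 50% and 84% of gene bodies at CpG. For shifts of 1 and 2 points, chosen after the data were seen, it recovered 0% of gene bodies at CH. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with version 1.17.8 of data.table.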

Results

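Cytosine methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads the CpG-dense part of the genome base by base, in nuclei of pyramidal neurons from the medial prefrontal cortex of male C57BL/6 mice aged 6 to 8 weeks. The nuclei had been sorted for the pyramidal marker SATB2, for GFP from the virus and for DAPI. The 4 PFC DKO samples came from mice with floxed Dnmt1 and Dnmt3a, genes for the maintenance and a de novo DNA methyltransferase, injected on each side with 200 nL of a virus that expresses Cre and GFP in neurons. The 4 Control samples came, per the labels, from wild-type mice given the same vector. The deposited names of the Control libraries carry GFP and those of PFC DKO Cre. It is open whether the Control virus also expressed Cre. The title of the series ties this deletion to a lower intake of palatable food, and the libraries ask where methylation differs in the targeted neurons. The labels do not say that each sample is a separate mouse, so p-values measure only the spread between these samples, which may be technical.

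Coverage summed over cytosines ran from 36308862 to 76150878 reads per library at CpG cytosines. It ran from 217456229 to 428718866 at CH cytosines, those followed by A, C or T. A read that spans several cytosines counts at each, here and wherever reads of a library, window, tile or gene region are given. Between 681806 and 1109752 CpG cytosines per library had at least 10 reads, with a median of 35 to 45 reads at these. Of these sites, 91.5% to 94.5% stood at exactly 0 or 100% in a given library. Only 19209 CpG and 104133 CH cytosines had 10 reads in all 8 libraries, and the comparisons below use these shared sites unless stated. A wider set, chosen after the data were seen, held 359844 CpG and 1692053 CH cytosines with 10 reads in at least 2 libraries per group.

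Methylation does not show whether the floxed parts were lost, and the values at the targeted genes therefore do not check the labels. Neither gene's CpG-rich end was read in enough libraries to be tested. Across Dnmt1 (mm10, chromosome 9, 20907206 to 20959888, with 1000 bp on each side), CpG methylation averaged 42.1% ± 1.61 (SD, n = 4) in Control and 42.1% ± 7.68 (SD, n = 4) in PFC DKO on site-centred values (exact permutation p = 1). Across Dnmt3a (chromosome 12, 3801559 to 3914443), it averaged 19.7% ± 4.03 (SD, n = 4) in Control and 22.6% ± 1.27 (SD, n = 4) in PFC DKO, a difference of 2.92 points (95% interval −3.01 to 9.15, exact p = 0.257). CH methylation was 1.61% ± 1.28 and 1.23% ± 0.539 at Dnmt1 (exact permutation p = 0.714). At Dnmt3a it was 1.07% ± 0.552 and 0.410% ± 0.316 (exact permutation p = 0.0857). These values rest on 6 to 30 CpG sites per library at Dnmt1 and 14 to 66 at Dnmt3a. In the gene body of Dnmt3a, 7 shared CpG sites gave 77.8% ± 9.29 and 87.0% ± 5.44 (limma-moderated quasi-binomial adjusted p = 0.716).

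CpG methylation of the sorted neurons, averaged over the shared sites or the wider set, did not differ detectably between the genotypes. At the shared sites it averaged 71.4% ± 0.424 (SD, n = 4) in Control and 71.1% ± 0.437 (SD, n = 4) in PFC DKO, a difference of −0.302 points (95% interval −1.34 to 0.551, exact permutation p = 0.343). A fall of more than 1.34 points at these sites lies outside the interval. On the wider set the difference was −0.225 points (exact p = 0.229). The averages depended on which sites were read. Over every site of its own with 10 reads, each library gave 47.6% ± 1.47 in Control and 58.3% ± 6.75 in PFC DKO, a difference of 10.7 points in the opposite direction (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The libraries differed in their sites: 28.6% ± 0.867 of Control sites and 22.4% ± 4.06 of PFC DKO sites lay in CpG-rich gene ends (exact permutation p = 0.0286). PFC DKO replicates 1 and 3 stood apart with 18.6% and 19.2% of sites in gene ends and own-site levels of 64.9% and 63.2%, against 25.6%, 26.2%, 52.8% and 52.1% in replicates 2 and 4. Without these 2 libraries the shared-site difference was −0.670 points (exact permutation p = 0.133).

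**Figure D1:**
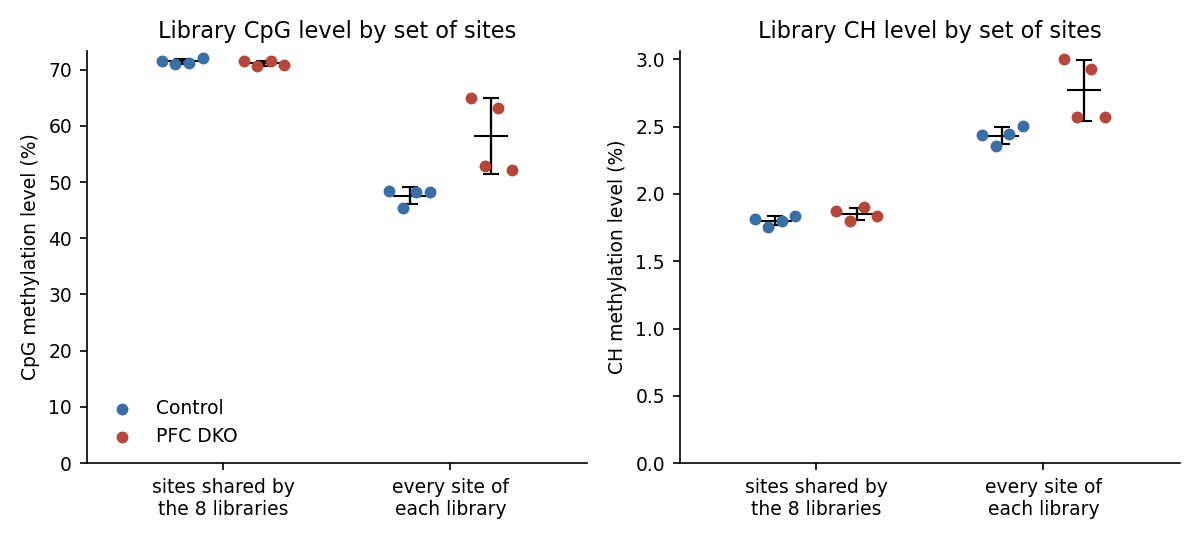
Mean methylation in percent (y axis) of each library at CpG and CH cytosines, over sites shared by the 8 libraries and over each library's own sites, for Control and PFC DKO; points are libraries and bars are mean ± SD (n = 4). At shared CpG sites the groups lie at 71.4% and 71.1%, and over own sites at 47.6% and 58.3%.

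Non-CpG methylation, which in the brain marks mature neurons and is laid down by Dnmt3a, did not differ detectably in its mean. Pooled over the shared CH sites it was 1.80% ± 0.0345 (SD, n = 4) in Control and 1.85% ± 0.0459 (SD, n = 4) in PFC DKO, a difference of 0.0514 points (95% interval −0.0397 to 0.150, exact permutation p = 0.171). A single 10 kb window on chromosome 2 (mm10, 98660001 to 98670000), which lies in no gene, took 69.1% to 72.2% of these reads, and without it the difference turned to −0.0539 points (exact permutation p = 0.143). Whether the many reads of this window come from a single locus was not tested, so its levels may not be those of a single locus. Inside the window, CH methylation was 0.987% ± 0.0124 in Control and 1.13% ± 0.0973 in PFC DKO when reads were pooled, but 3.34% ± 0.240 and 2.60% ± 0.345 when its 256 sites counted equally (exact permutation p = 0.0286 for both, in opposite directions). The same window held 64.1% to 74.7% of shared-site CpG reads, with pooled CpG levels of 98.0% ± 0.153 and 94.9% ± 2.06 (exact permutation p = 0.0286) and equally weighted levels of 89.5% ± 1.601 and 90.2% ± 1.23 (exact permutation p = 0.457). Over the wider set, mean CH methylation was 2.59% ± 0.0373 and 2.60% ± 0.0373, a difference of 0.00819 points (95% interval −0.0923 to 0.0731, exact permutation p = 0.8286). CH calls on the mitochondrial genome, used as a measure of incomplete conversion, were 0.524% ± 0.253 in Control and 1.17% ± 0.280 in PFC DKO (exact permutation p = 0.0286). At the 53 mitochondrial CH sites shared by the 8 libraries they were 0.530% ± 0.283 and 0.900% ± 0.136 (exact permutation p = 0.0857). CpG calls on the mitochondrial genome went the other way, at 3.20% ± 2.30 in Control and 2.05% ± 0.899 in PFC DKO (exact permutation p = 0.514). Subtracting the CH level over all mitochondrial reads turned the pooled difference to −0.597 points (exact permutation p = 0.0286). Subtracting that of the shared sites, chosen after the data were seen, turned it to −0.318 points (95% interval −0.727 to 0.141, exact permutation p = 0.114). Sites followed by a C, chosen likewise, differed by −0.00319 points on the wider set (95% interval −0.0304 to 0.0271). At the shared sites they differed by 0.489 points (95% interval 0.129 to 0.925), and by 0.0348 without the window (95% interval −0.0357 to 0.114). The mitochondrial difference of 0.648 points had a 95% interval of 0.0844 to 1.32. Both shared-site intervals overlap it, and the first includes 0.648. Only the wider-set interval stands clear of it, which argues against an equal rise in incomplete conversion at the wider-set sites. At the shared sites such a rise stays open. The subtracted differences therefore do not show a CH loss.

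By genomic feature, the neurons had lower methylation in CpG-rich gene ends than in gene interiors, and no feature class passed the threshold between the genotypes. CpG-rich gene ends stood at 30.3% ± 0.575 in Control and 29.96% ± 0.418 in PFC DKO over 2241 sites (exact permutation p = 0.343). Gene interiors stood at 72.1% ± 0.409 and 71.7% ± 0.469 over 8518 sites (exact permutation p = 0.286). Intergenic sites stood at 81.7% ± 0.482 and 81.5% ± 0.449 over 8450 sites (exact permutation p = 0.714). The 329 shared sites of the X chromosome gave 80.3% ± 1.15 and 79.8% ± 1.34 (exact permutation p = 0.657), and the 18880 autosomal sites differed by −0.299 points (exact permutation p = 0.4). Among classes of mean level, sites under 20% were at 5.31% ± 0.671 in Control and 4.57% ± 0.161 in PFC DKO, a difference of −0.735 points (95% interval −1.46 to 0.133, exact permutation p = 0.0857, adjusted over the features 0.686). The classes from 20 to 80% and over 80% differed by −0.670 and −0.0781 points (exact permutation p = 0.543 and p = 0.771). The adjusted exact permutation p of every other class was 0.771. For the class under 20%, the difference had an exact permutation p of 0.0286 without Control replicate 3 (−0.959 points) and on the wider set (−0.474 points, adjusted 0.229). On the wider set each PFC DKO library (1.35% to 1.67%) lay below each Control (1.82% to 2.09%). An adjusted 0.229 is the lowest that 1 class alone can reach over these classes. Missing the threshold therefore does not show that the levels are equal. The sign was not fixed for several classes: without Control replicate 4 the intergenic difference was 0.0194 and that of the class from 20 to 80% 0.0947 points, without PFC DKO replicates 2 and 4 in turn that of the class over 80% was 0.0943 and 0.0554, and on the X it was 0.460 without PFC DKO replicates 1 and 3.

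Of single CpG sites and 1 kb tiles, none passed the test between the genotypes. The limma-moderated quasi-binomial test called 0 of 19209 sites (1262 at an unadjusted p under 0.05), while edgeR called 1 (388 at an unadjusted p under 0.05). At 3 molecules per library, near the effective number here, it recovered 0% of simulated changed sites, so 0 calls do not show equal sites. The quasi-binomial test called 0 of 1791 tiles (169 unadjusted), and edgeR called 0 (57 unadjusted). The tiles of smallest p with lower values in PFC DKO lay between genes. In the most covered window, 1030828 bp from Lrrc4c, a netrin-G ligand gene, the tile at 98662001 to 98663000 of chromosome 2 had 96.7% ± 0.596 (SD, n = 4) in Control and 92.6% ± 1.30 (SD, n = 4) in PFC DKO (adjusted p = 0.184, limma-moderated). This tile held 890722 to 1975454 reads per library over its 28 sites, which may not come from a single locus. The tile at 75085001 to 75086000 of chromosome 15, 22661 bp from Ly6c2, had 96.9% ± 0.2998 and 85.8% ± 6.80, and that at 151079001 to 151080000 of chromosome 1, 85848 bp from Hmcn1, a basement membrane gene, had 98.5% ± 1.71 and 89.1% ± 12.6 (adjusted p = 0.308 for both). Tiles with higher values in PFC DKO were those next to Arsi, 15216 bp from Sfpq, an RNA-binding factor gene, at 0.115% ± 0.154 and 5.88% ± 5.27, and in Msi1, a neural RNA-binding protein gene, at 97.3% ± 1.03 and 100.0% ± 0.0608 (adjusted p = 0.184, 0.241 and 0.241). The Arsi tile holds the same 3 CpG sites as the Arsi gene end described below, so it is not a separate change. Without PFC DKO replicates 1 and 3, the Ly6c2 tile alone was called (−5.84 points, adjusted p = 0.00780, limma-moderated).

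Limma on the wider set called 4 of 14562 tiles, 2 lower and 2 higher in PFC DKO (550 at an unadjusted p under 0.05). The tile in Slc6a17, a synaptic vesicle amino acid transporter gene (chromosome 3, 107473001 to 107474000), fell from 100% ± 0 to 75% ± 0 (SD, n = 3 per group, limma adjusted p = 0.000554). A tile 20971 bp from Fam136a (chromosome 6, 86344001 to 86345000) fell from 19.08% ± 2.01 (n = 4) to 0.338% ± 0.3003 (n = 3, limma adjusted p = 0.0281). The tile at Otog, an inner ear protein gene (chromosome 7, 46241001 to 46242000), rose from 66.7% ± 0 to 90.1% ± 0.210 (SD, n = 3 per group, limma adjusted p = 0.000860). The Otog gene end overlaps this tile and had the same difference of 23.4 points (limma adjusted p = 0.000393), so it is not a separate change. The tile in Tmprss11c, a serine protease gene (chromosome 5, 86282001 to 86283000), rose from 83.2% ± 1.15 to 97.9% ± 2.14 (limma adjusted p = 0.0281). All 4 regions were taken from a site set chosen after the data were seen. The SDs of 0 at Slc6a17 (4 CpG sites) and in the Otog Controls (3 CpG sites) leave little measured spread behind their small p-values. Of the 35 splits of the libraries, 24 called as many tiles, so chance could not be excluded. The counts moved with each library left out, from 1 lower tile without PFC DKO replicate 3 to 10 without replicate 2, and from 1 higher tile without Control replicate 3 to 7 without PFC DKO replicates 1 or 4 in turn, and stood at 8 and 9 without PFC DKO replicates 1 and 3 together. Gene ends called higher on this set ranged from 1 to 5 (without PFC DKO replicate 2), and 1 lower end was called without Control replicate 1.

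At CpG-rich gene ends, 1 gene passed the test: Arsi, which encodes an arylsulfatase, with higher values in PFC DKO. With 6 of the 35 splits of the libraries calling as many ends, chance could not be excluded. The Arsi end (mm10, chromosome 18, 60910991 to 60912491) went from 5.79% ± 5.13 (SD, n = 4) in Control to 34.5% ± 5.60 (SD, n = 4) in PFC DKO, a difference of 28.8 points over 3 CpG sites and 111 to 1117 reads per library. The limma-moderated quasi-binomial adjusted p was 0.0320 over 324 gene ends, of which 36 had an unadjusted p under 0.05. The call was lost with edgeR (adjusted p = 0.838), which called 0 ends (12 unadjusted), on the wider set (17.4 points, limma adjusted p = 0.839), with unmoderated dispersion (0.157), with ends of at least 1 site included (0.0576) and with a wider window (0.0528). It was also lost without Control replicates 1, 2 or 4 (adjusted p = 0.120, 0.0750 and 0.0549, limma-moderated), without each PFC DKO replicate (0.0745, 0.0601, 0.103 and 0.272 for replicates 1 to 4) and without PFC DKO replicates 1 and 3 together (0.185). In these left-out runs the difference stayed between 26.8 and 31.2 points. The other ends of smallest p did not pass (adjusted p = 0.425 for each, limma-moderated). Gsx1, a homeobox gene of forebrain patterning (chromosome 5, 147187696 to 147189196), had 9.91% ± 2.80 in Control and 0% in every PFC DKO library over 6 sites with 94 to 246 reads. Dusp15, a phosphatase gene (chromosome 2, 152951900 to 152953400), had 7.49% ± 8.87 and 0% with 32 to 351 reads per library, and Cwf19l1 (chromosome 19, 44135376 to 44136876) had 5.89% ± 6.64 and 0.415% ± 0.378. With higher values in PFC DKO, Sec14l4, a lipid-binding protein gene, had 97.5% ± 2.03 and 100.0% ± 0.0434, and Psme2, a proteasome activator gene whose end is shared with Rnf31, had 0.0264% ± 0.0528 and 1.04% ± 1.65.

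For gene bodies at CpG, the limma-moderated quasi-binomial test called 0 of 407 genes (33 at an unadjusted p under 0.05), and edgeR called 0 (21 unadjusted). The gene nearest to a call was Hoxb3, a homeobox gene of the hindbrain (mm10, chromosome 11, 96307101 to 96347930), with 11.5% ± 4.76 (SD, n = 4) in Control and 0.443% ± 0.562 (SD, n = 4) in PFC DKO (limma-moderated adjusted p = 0.118). Lrrc66 (chromosome 5, 73606642 to 73632421) had 73.6% ± 11.9 and 37.1% ± 19.5, and Cdk8, the kinase of the Mediator complex (chromosome 5, 146230795 to 146302874), 27.8% ± 5.22 and 17.4% ± 3.20 (adjusted p = 0.461 for both). In the opposite direction, Map3k5, a stress-activated kinase gene (chromosome 10, 19934101 to 20142750), had 86.1% ± 7.57 and 99.7% ± 0.502 (adjusted p = 0.250). Tle1, a transcriptional corepressor gene (chromosome 4, 72109945 to 72200989), had 3.61% ± 4.12 and 32.8% ± 23.3, and Hlcs, the biotin ligase gene (chromosome 16, 94129306 to 94315239), 15.2% ± 6.88 and 26.1% ± 6.80 (adjusted p = 0.461 for both). Cdk8 passed without Control replicate 2 (−12.9 points, adjusted p = 0.0447) and Socs2, chosen after its values were seen, without PFC DKO replicate 4 (46.7 points, adjusted p = 0.0182, limma-moderated). Limma on the wider set called 0 of 5895 gene bodies (412 unadjusted).

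**Figure D2:**
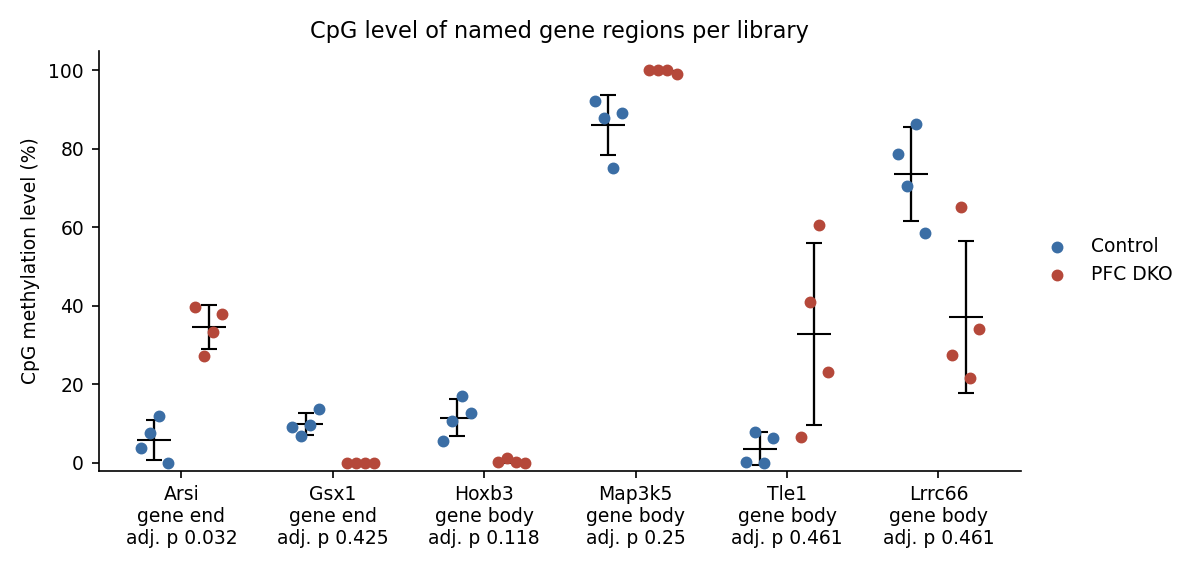
CpG methylation in percent (y axis) of the Arsi and Gsx1 gene ends and the Hoxb3, Map3k5, Tle1 and Lrrc66 gene bodies in Control and PFC DKO; points are libraries, bars are mean ± SD (n = 4) and each panel gives its adjusted p. Only Arsi passed, with Control at 5.79% ± 5.13 and PFC DKO at 34.5% ± 5.60.

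For gene bodies at CH, only 25 genes had 50 shared sites, and the limma-moderated test called 0 (1 at an unadjusted p under 0.05), as did edgeR (0 unadjusted). Tenm3, a teneurin of synaptic wiring (mm10, chromosome 8, 48225665 to 49522824), had 6.87% ± 0.624 (SD, n = 4) in Control and 5.32% ± 0.752 (SD, n = 4) in PFC DKO (limma-moderated adjusted p = 0.762). Gse1 had 4.56% ± 2.05 and 3.10% ± 0.735, and Zfhx3, a neuronal transcription factor gene, 5.94% ± 1.596 and 4.61% ± 1.35. Values were higher in PFC DKO at Spock1, a proteoglycan gene (1.19% ± 1.17 and 1.84% ± 1.59), Anks1b, a postsynaptic density gene (2.14% ± 1.17 and 2.87% ± 1.42), and Sfi1, a centrosomal gene (1.32% ± 0.197 and 1.44% ± 0.345), each with an adjusted p of 0.762. On the wider set limma called 0 of 6810 gene bodies (432 unadjusted). That test recovered 0% of simulated shifts of 1 or 2 points. On the wider set the sign turned for Tenm3 (0.0683 points), Zfhx3 (0.122), Spock1 (−0.464), Anks1b (−0.159) and Sfi1 (−0.464).

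Of the 15 gene lists, only 4 comparisons had 3 measured members at the shared sites, and none passed. At gene ends, 3 of 26 glutamate receptor genes had 1.04% and 0.554% (exact permutation p = 0.6, with a median difference of the opposite sign, 0.120 points) and 3 of 21 interneuron markers 9.60% and 10.1% (exact permutation p = 0.943). In gene bodies at CpG, 8 of 31 postsynaptic genes had 61.7% and 58.6% (exact permutation p = 0.571), and clustered protocadherins 52.4% and 59.3% (exact permutation p = 0.6). The 11 measured protocadherins share the same 5 CpG sites and count as 1 region, and its difference turned from 6.82 to −0.924 points without PFC DKO replicate 1 and to −6.79 without replicates 1 and 3. The postsynaptic difference went from −3.10 to −0.0631 points without Control replicate 4, and both gene end differences turned sign with 1 library left out. The group values that follow come from the wider set. There, 0 of 195 members at gene body CpG, 0 of 201 at gene body CH and 0 of 86 at gene ends passed limma over all genes, and 0 when adjusted over the list alone, with 15, 11 and 2 members at an unadjusted p under 0.05. The smallest adjusted exact permutation p of a list was 0.143 at gene body CpG, 0.429 at gene body CH and 0.867 at gene ends. Over 15 lists, 0.429 is the lowest that 1 list alone can reach. When 3 lists reach the smallest p of the exact test, the lowest is 0.143. Missing the threshold therefore does not show that the levels of a list are equal. With 1 library left out, the sign turned for 3 of 15 lists at gene body CpG, 7 of 15 at gene body CH and 7 of 14 at gene ends. PFC DKO replicates 1 and 3, which had fewer sites in gene ends, enter all of these lists.

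Among receptors, the monoamine, opioid and cannabinoid group had the widest gap in CH methylation. Its 11 measured gene bodies averaged 2.94% ± 0.156 (SD, n = 4) in Control and 1.83% ± 0.667 (SD, n = 4) in PFC DKO, 8 lower and 3 higher, a difference of −1.11 points (exact permutation p = 0.0286, adjusted 0.429; median difference −1.10, p = 0.0857). PFC DKO replicates 1 and 3 stood at 1.34% and 1.18% and replicates 2 and 4 at 2.51% and 2.29%. Without the first 2 the difference was −0.539 points (exact permutation p = 0.0667). Adra1a, an adrenergic receptor gene, had 5.13% ± 1.62 (n = 3) and 2.06% ± 0.918 (limma adjusted p = 0.773), and Htr4, a serotonin receptor gene, 4.90% ± 1.28 and 2.60% ± 1.32 (limma adjusted p = 0.773). At CpG the 13 measured bodies of this group had 55.6% and 53.4% (exact permutation p = 0.2). Feeding peptides, hormones and their receptors, the group closest to the behaviour in the title, had 2.95% ± 0.152 and 2.35% ± 0.667 at CH over 11 genes, 9 lower and 2 higher (exact permutation p = 0.0857). PFC DKO replicate 3 alone stood at 1.39%, and without it the difference fell from −0.594 to −0.275 points (exact permutation p = 0.143). At CpG the feeding group had 55.6% and 55.7% over 12 genes (exact permutation p = 0.886). Of these, Fto, an obesity-linked demethylase gene, had 5.54% ± 1.52 and 3.92% ± 0.229 at CH, and Hcrtr2, an orexin receptor gene, 52.8% ± 4.71 (n = 3) and 65.2% ± 5.28 at CpG (limma adjusted p = 0.780 and 0.650). Glutamate receptors had 2.56% and 2.61% at CH over 23 genes (exact permutation p = 0.714) and 53.2% and 51.7% at CpG over 20, 13 lower and 7 higher (exact permutation p = 0.171). Among them Grik3, a kainate receptor subunit gene, had 50.4% ± 7.71 and 36.9% ± 2.22 at CpG (limma adjusted p = 0.650). GABA receptors had 1.46% and 1.42% at CH over 7 genes (exact permutation p = 0.914) and 40.3% and 38.7% at CpG over 8 (exact permutation p = 0.257), with Gabrb1 at 0.758% ± 0.512 and 1.85% ± 0.409 at CH (limma adjusted p = 0.773).

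**Figure D3:**
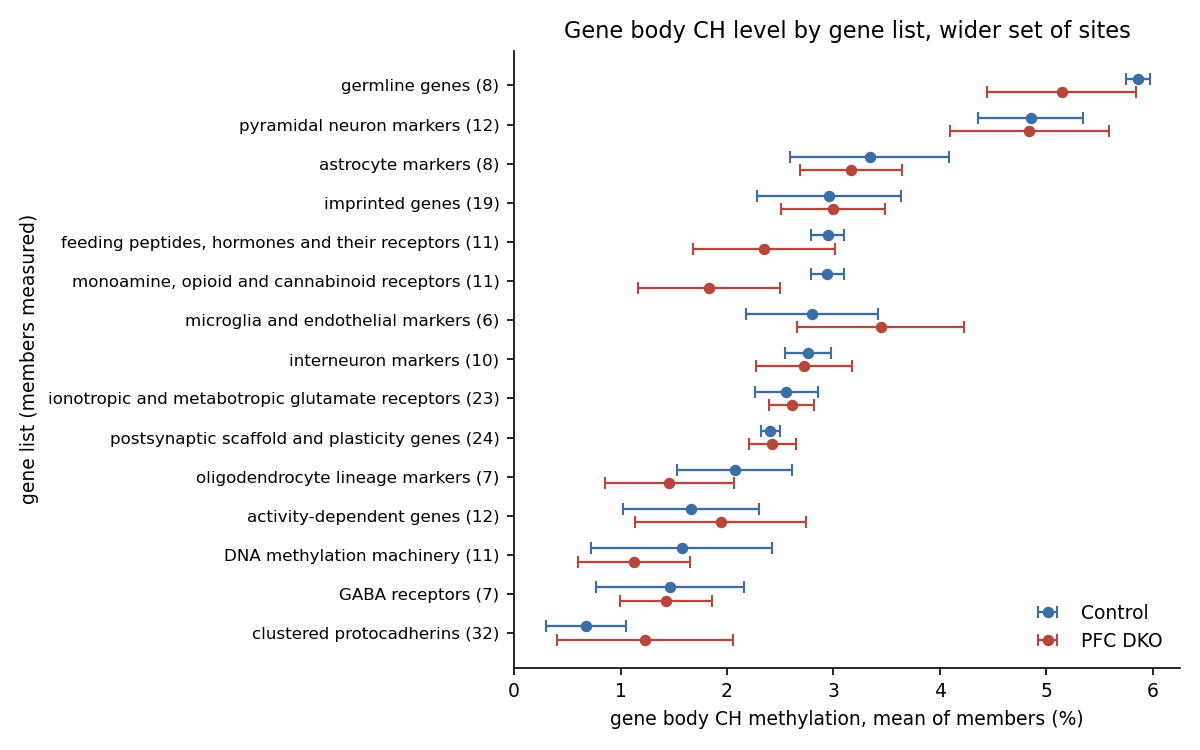
Mean gene body CH methylation in percent (x axis) of the measured members of each gene list (y axis), on the wider site set, in Control and PFC DKO; points are group means and error bars are SD (n = 4 libraries). The monoamine, opioid and cannabinoid receptors lie at 2.94% and 1.83%, and no list passed after adjustment. With so few libraries, a list on its own could not pass.

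Lists of synaptic and pyramidal neuron genes did not pass between the groups. Postsynaptic scaffold and plasticity genes had 2.41% ± 0.0857 in Control and 2.43% ± 0.220 in PFC DKO at CH over 24 genes (exact permutation p = 0.943) and 46.2% and 46.6% at CpG over 25 (exact permutation p = 0.971). Within them the presynaptic adhesion gene Nrxn1 had the smallest p at CH, with 0.624% ± 0.280 and 1.62% ± 0.348 (limma adjusted p = 0.732), and Nrxn2 had 0.331% ± 0.377 and 1.01% ± 0.651. Pyramidal neuron markers had 4.85% and 4.84% at CH (exact permutation p = 0.971) and 42.3% and 43.9% at CpG (exact permutation p = 0.114, with a median difference of −0.866 points), 12 genes each. At gene ends the layer marker Tle4 had 1.79% ± 2.01 and 7.88% ± 2.53 (n = 3, limma adjusted p = 0.839). Activity-dependent genes, which neuronal firing induces, had 17.1% ± 1.27 and 13.9% ± 1.11 at gene body CpG over 16 genes, 11 lower and 5 higher, a mean difference of −3.18 points (exact permutation p = 0.0286, adjusted 0.143) but a median difference of −0.471 (exact permutation p = 0.257). At CH their 12 bodies had 1.66% and 1.94% (exact permutation p = 0.629). Bdnf, the neurotrophin gene, had 6.14% ± 1.52 and 9.19% ± 2.87 at CpG, and Dusp4, a phosphatase gene, 16.6% ± 9.32 and 8.65% ± 1.82. Clustered protocadherins, adhesion genes whose bodies overlap and share sites, had 0.676% and 1.23% at CH over 32 genes, 5 lower and 27 higher (exact permutation p = 0.314), and 38.4% and 35.6% at CpG over 25, 20 lower and 5 higher (exact permutation p = 0.229).

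Among genes tied to methylation itself, the DNA methylation machinery had 45.2% ± 1.12 in Control and 42.8% ± 0.678 in PFC DKO at gene body CpG, a mean difference of −2.40 points (exact permutation p = 0.0286, adjusted 0.143), but 5 members lower and 7 higher and a median difference of 0.337 points. Its 11 bodies at CH had 1.57% and 1.13% (exact permutation p = 0.486). At CpG, Gadd45a, a gene of active demethylation, had 26.3% ± 21.6 and 3.44% ± 7.33 (limma adjusted p = 0.727), and Mbd5, a methyl-CpG-binding domain gene, 89.5% ± 7.74 and 80.8% ± 4.83 (n = 3, limma adjusted p = 0.740). Tet3, a methylcytosine dioxygenase gene, had 30.2% ± 1.65 and 32.4% ± 3.90 (limma adjusted p = 0.741). Imprinted genes had 54.7% and 51.2% at CpG over 16 bodies (exact permutation p = 0.286) and 2.96% and 3.00% at CH over 19 (exact permutation p = 0.886). Grb10, an imprinted growth regulator, had 73.9% ± 7.85 and 39.7% ± 16.9 at CpG and 4.65% ± 1.41 and 1.96% ± 1.85 at CH (limma adjusted p = 0.650 and 0.780). Germline genes, which somatic cells silence, had 72.4% and 71.9% at CpG (exact permutation p = 0.886) and 5.86% ± 0.112 and 5.14% ± 0.701 at CH (exact permutation p = 0.114) over 8 bodies each. Of these Tdrd6, a germ cell granule gene, had 5.57% ± 1.72 and 2.65% ± 2.44 (n = 3) at CH.

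Markers of the cell types outside the sort did not pass either. Interneuron markers had 30.4% ± 1.19 in Control and 27.5% ± 0.772 in PFC DKO at gene body CpG over 12 genes, 9 lower and 3 higher, a mean difference of −2.93 points (exact permutation p = 0.0286, adjusted 0.143) and a median difference of −1.35 (exact permutation p = 0.2). At CH they had 2.76% and 2.72% (exact permutation p = 0.943). Among them Erbb4, the neuregulin receptor gene, had 46.7% ± 0.786 and 40.1% ± 6.12 at CpG, and Adarb2 5.07% ± 1.41 and 3.08% ± 0.583 at CH. Astrocyte markers had 48.7% and 51.6% at CpG over 6 genes (exact permutation p = 0.314, with a median difference of −0.576 points) and 3.34% and 3.17% at CH over 8 (exact permutation p = 0.743), with Gli3, a Hedgehog pathway gene, at 8.57% ± 2.59 and 4.52% ± 1.24. Oligodendrocyte lineage markers had 62.6% and 64.5% at CpG over 6 genes (exact permutation p = 0.343) and 2.07% and 1.46% at CH over 7, all 7 lower (exact permutation p = 0.2). Microglia and endothelial markers had 73.4% and 67.6% at CpG over 4 genes (exact permutation p = 0.171, with a median difference of 0.706 points) and 2.80% and 3.45% at CH over 6 (exact permutation p = 0.286). Mean and median also differed in sign at CH for the postsynaptic, GABA receptor, activity-dependent, pyramidal, interneuron and astrocyte lists, each with a median difference between −0.0931 and 0.127 points.

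At gene ends no list differed detectably on the wider set, with wide intervals for some. The methylation machinery had 1.61% and 2.03%, glutamate receptors 9.61% and 11.1%, postsynaptic genes 1.91% and 1.24%, GABA receptors 2.61% and 0.815%, and monoamine, opioid and cannabinoid receptors 1.89% and −0.0292%, a site-centred mean that can fall below 0. Feeding genes had 3.77% and 3.21%, activity-dependent genes 1.601% and 1.17%, pyramidal markers 4.03% and 5.83%, interneuron markers 6.84% and 6.74%, astrocyte markers 1.35% and 0.800%, and oligodendrocyte markers 19.004% and 18.8%. Means and medians differed in sign for the last 3 of these lists. Imprinted genes had 22.2% and 27.9% (95% interval of the difference −16.4 to 32.1), germline genes 57.7% and 60.7%, and protocadherins 13.8% and 19.9%, with exact permutation p of 0.514, 0.114 and 0.2. With 1 library left out the imprinted difference of 5.68 points ranged from 0.353 to 9.71. Microglia and endothelial markers had fewer than 3 measured ends.

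The authors' deposited table lists 148709 CpG sites as different between the pooled groups, 76867 lower and 71842 higher in PFC DKO, each by at least 30 points. Of the sites in the authors' deposited table, 39588 (26.6%) differ by 100 points. The pooled call counts gave the same difference within 0.01 points at all 148709 sites. Of them, 36984 (24.9%) had 10 reads in only 1 library of each group, and 107712 (72.4%) in only 1 library of at least 1 group. At the 571 of these sites that entered the replicate-aware test, 0 passed over all sites and 0 over the deposited list alone (smallest adjusted p = 0.0505, limma-moderated), while edgeR called 1 of 19209 sites in all. With 3 molecules per library that test recovered 0% of simulated changes, and the libraries here had an effective 1.59 to 3.65. The count of 0 therefore does not show that these sites are equal. The 4 libraries of each group did not overlap at 65 of the 571 sites (11.4%). Chance gives 2.86% at sites without ties that were not picked by their difference, but these were picked. Ties at 0 or 100% would change that share. Among the sites of at least 30 points under each other split, 36 to 65 did not overlap. In all, 3 of the 35 splits gave as many as the real one.

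The sites named next are those of the widest differences among the 571 measured in all 8 libraries, not in the whole of the comparison. For a site in Robo2, an axon guidance receptor gene (mm10, chromosome 16, 73916243), the authors' deposited table gives a rise of 75.7 points. There the library means were 18.6% ± 23.8 (SD, n = 4) in Control and 99.8% ± 0.400 (SD, n = 4) in PFC DKO (limma-moderated adjusted p = 0.471). Among these 571 sites, the other widest rises in the authors' deposited table were 94.8 points for a site 57650 bp from Tnks (chromosome 8, 35023340), 81.1 in Pax6os1 (chromosome 2, 105603960), 73.1 in Fanci (chromosome 7, 79397444) and 69.9 in Bcl3 (chromosome 7, 19817173). The widest falls among them in the authors' deposited table were −88.9 points in Ednrb, an endothelin receptor gene (chromosome 14, 103815855), −72.8 in Ildr2 (chromosome 1, 166296580), −69.1 in Ccdc88b (chromosome 19, 6847670), −67.5 in Tacc1 (chromosome 8, 25179237) and −66.0 in Camk2b, a calcium-dependent kinase gene of synapses (chromosome 11, 5987153). Per library, Ednrb had 91.5% ± 17.0 in Control and 0% in every PFC DKO library (limma-moderated adjusted p = 0.632), while Camk2b had 75% ± 50 and 50% ± 57.7 (adjusted p = 0.771). With each site counted once per list, the sites of the authors' deposited table made up 11.4% of the tested sites in protein-coding genes, 29.3% in imprinted genes (334 lower, 299 higher) and 32.4% in clustered protocadherins (110 lower, 113 higher). The share in the authors' deposited table was 17.3% for postsynaptic genes, 16.02% for microglia and endothelial markers, 15.9% for pyramidal markers, 14.7% for glutamate receptors, 14.3% for GABA receptors, 14.1% for both germline genes and interneuron markers, and 13.9% for oligodendrocyte markers. It was 13.1% for monoamine, opioid and cannabinoid receptors, 12.3% for feeding genes (127 lower, 114 higher), 10.3% for astrocyte markers, 9.63% for the methylation machinery and 8.67% for activity-dependent genes (146 lower, 96 higher) in the authors' deposited table. These shares were not matched for methylation level or set against other splits of the libraries. They therefore do not tie a list to the deletion.

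**Figure D4:**
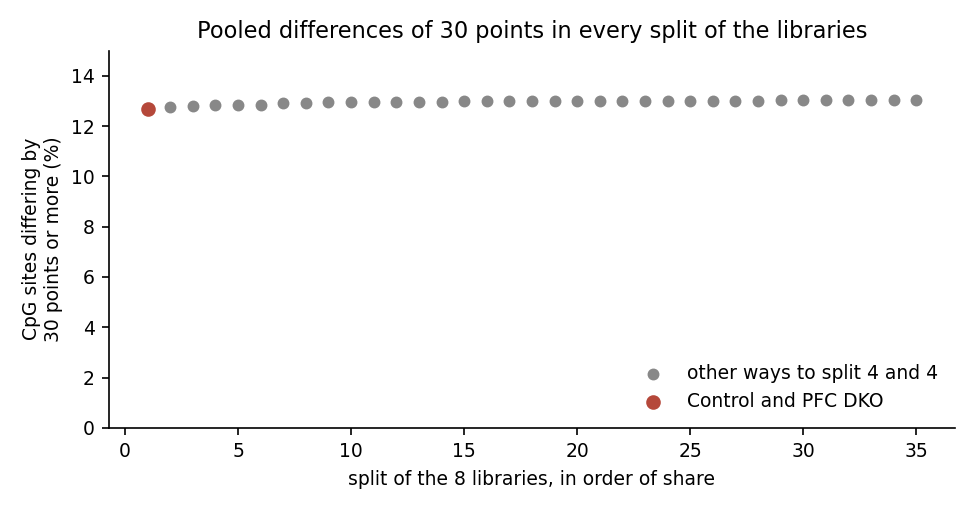
Percent of CpG sites (y axis, from 0) that differ by at least 30 points between pooled groups for each of the 35 splits of the 8 libraries into 4 and 4 (x axis, in order of share), the real split of Control and PFC DKO marked. The real split gives 12.7% and the highest other split 13.05%. Each split compares its own set of sites.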

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

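The tests of the own-site levels, of the deposited differences and of the splits were chosen only after the results were seen, and the tests of the most covered window before.

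Over each library's own sites, CpG methylation was 10.7 points higher in PFC DKO. At sites shared by the 8 libraries the difference was −0.302 points, and its 95% interval ended at 0.551 points, far below 10.7. This argues against a gain of methylation at the shared sites as the source. Reading different sites may account for the pattern, since fewer PFC DKO sites lay in gene ends, and at sites also read in another Control library the PFC DKO libraries averaged 49.2% against 49.5% in those Controls. Why the libraries hold different sites, in PFC DKO replicates 1 and 3 above all, stays open.

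The authors' deposited table holds 148709 sites that differ by at least 30 points. Among all sites with a library in each group, the real split gave such a difference at 12.7%. All 35 splits of the 8 libraries gave at least that share, the highest other 13.046%. The splits compared different sites, 1176300 in the real one and up to 1370352 in others. The share ran from 2.99% to 14.0% with the number of libraries per group, so the rank of the real split is not read. Pairs of single libraries differed by over 30 points at a median of 13.4% of sites within a group and 13.5% between groups. Within Control the pairs gave 12.5% to 13.03%, within PFC DKO 13.8% to 15.6%, and between groups 12.9% to 14.2%. Each pair compared its own sites. Control pairs, without the deletion, came close to the share between groups. This argues against the deletion of Dnmt1 and Dnmt3a as the source of most of the deposited differences. The shares among PFC DKO pairs lay above those of every Control pair, and the cause of this was not tested. Few DNA molecules behind each site could account for such differences: the strands of a CpG within 1 library differed like draws of at most 1.22 molecules, and by over 30 points at 15.95% to 18.5% of CpGs. Hemimethylation would add to this strand difference and was not separated from it. At the shared sites, where 571 reached 30 points, the other splits gave 426 to 582 and 2 of 35 as many as the real one, so a small part tied to the genotype stays open there.

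In the 10 kb window of chromosome 2 that took most shared reads, read-weighted CpG methylation was 3.05 points lower in PFC DKO (−3.05, exact permutation p = 0.0286). With its 66 sites weighted equally the difference was 0.752 points (95% interval −2.17 to 3.61, exact permutation p = 0.457). The interval leaves out −3.05, which argues against an equal loss across the window, while a smaller loss stays open. A different spread of reads over the sites of the window may account for the read-weighted difference.

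Other splits of the 8 libraries into 4 and 4 gave as many calls as the real split. Chance could not be excluded for the counts above 0, and a count of 0 tests nothing, as every split reaches it. For CpG sites the real split called 0 and the highest other 2 (35 of 35 splits as many), for sites with 3 libraries per group 0 and 0 (35), for tiles 0 and 2 (35), for gene bodies at CpG 0 and 1 (35) and at CH 0 and 1 (35). Counted at an unadjusted p under 0.001 in place of calls, the real split gave 36 CpG sites and the highest other 42 (2 of 35 as many), 50 and 58 with 3 libraries per group (4), 4 and 10 tiles (27), and 1 and 3 gene bodies at CpG (18). On the wider set such counts were 5 and 11 gene bodies at CpG (21) and 8 and 10 at CH (7), so chance could not be excluded for these either. For CpG-rich gene ends, where Arsi was called, the real split called 1 and the highest other 2 (6 of 35 splits as many). On the wider set the real split called 4 tiles and the highest other 9 (24 of 35), 1 gene end and 3 (19 of 35), and 0 gene bodies with 0 in every other split at CpG (35) and at CH (35).

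Single libraries lay far from the others of their group in 7 of 94 groups of 4 values checked, where chance picks out about 1 in 20. Control replicate 2 had an own-site CpG level of 45.4% (others 48.2% to 48.4%) and 76150878 CpG reads (others 43655545 to 49138664). Control replicate 4 had 72.7% in gene interiors (others 71.9% to 72.0%) and 44.5% at Dnmt1 (others 41.1% to 41.5%). The Psme2 gene end was at 0.106% in Control replicate 3 and 0% in the others. Among PFC DKO libraries, the Hoxb3 body was at 1.28% in replicate 2 (others 0.0457% to 0.238%) and the Map3k5 body at 99.0% in replicate 4 (100% in the others). The CH level on the mitochondrial genome, outside the compared chromosomes, was 0.648 points higher in PFC DKO, and 0.370 points higher at the sites shared by the 8 libraries (exact permutation p = 0.0857).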

How the results depend on the processing

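All settings named here as added were chosen after the data were seen: the wider set, the mitochondrial level at shared sites, X, the most covered window or PFC DKO replicates 1 and 3 left out, sites split by a following C, and Fisher's test with no minimum difference. The effective number of molecules per site was 1.59 to 3.65, from a spread between libraries that may include differences between samples. Simulated changes were recovered for 0% of sites at 3 molecules per library and for 3% at 10. Of 294 alternatives for the 18 named gene results, 271 kept direction and side of the threshold, 14 lost the call (all Arsi, adjusted p from 0.0247 to 0.839 over its alternatives), 1 gained it (Cdk8) and 8 moved. Except where stated, the cause was not tested.

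The mean CpG difference kept its sign (−0.447 to −0.111 with 1 library left out) except over own sites (10.7, different sites). The mean CH difference (0.0342 to 0.0701 with 1 library left out) was 0.335 over own sites and 0.489 at sites followed by a C, both with exact permutation p = 0.0286. With the mitochondrial level subtracted it was −0.597 (−0.318 with that of shared sites). Without the window it was −0.0539, 0.0348 at sites followed by a C (exact permutation p = 0.229) and −0.0818 at the others. At sites followed by a C in the wider set it was −0.00319. As a mean of site percentages the CH difference was 0.00824 (exact permutation p = 0.914). It was 0.0229 with the most covered sites left out and 0.0165 without PFC DKO replicates 1 and 3. Without sites over 50% in every library it was 0.0619. Among features, leaving out 1 library gave −0.959 to −0.539 for sites under 20%, −0.339 to 0.0194 for intergenic sites, −1.12 to 0.0947 for 20 to 80% and −0.258 to 0.0943 for over 80%. The wider set gave −0.474 for under 20% and 0.277 for over 80%. For X the difference was 0.580 with 20 reads and 0.460 without PFC DKO replicates 1 and 3.

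Fisher's exact test on pooled reads, which leaves out the spread between libraries, called 290 sites lower and 281 higher at the stricter threshold, and 5334 and 5032 at adjusted p under 0.05. edgeR called 1 site higher, at 98666956 of chromosome 2, in the most covered window. Tiles called were 1 lower without PFC DKO replicates 1 and 3, and 2 lower and 2 higher on the wider set. Gene ends called higher went from 1 to 0 with unmoderated dispersion, the stricter threshold, edgeR, at least 1 or 10 sites, the wider window and without PFC DKO replicates 1 and 3, and ranged from 0 to 1 with 1 library left out. Gene bodies called at CpG ranged from 0 to 1 in each direction with 1 library left out. Groups did not overlap at 65 deposited sites.

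With the replicate number as a block, 1 tile was called lower, at 98662001 to 98663000 of chromosome 2 (−4.04 points), and 1 higher, at 117478001 to 117479000 of chromosome 10 (60.2 points, 101502 bp from Cpsf6), both with a limma-moderated adjusted p of 0.0228, and 0 gene ends (Arsi 0.233); it changed no other call. Libraries of the same number did not deviate together (r across sites −0.0154 to 0.0309, other pairs −0.0211 to 0.0342), and 1 of 4 Control libraries correlated best with its own number, so the numbers were not taken to pair the samples. At least 200 CH sites per gene body left no gene to test, and exon and CA, CC and CT classes were not run.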

Other observations

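All tests in this part were chosen only after the levels were seen, and the values describe the 8 libraries together on the wider site set. Medians took the place of means once the level of Foxp2 had been seen to set the mean of its list.

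Gene lists differed in methylation level within these neurons far more than between genotypes. Germline genes, silenced by methylation in somatic cells, had a median gene end level of 75.4% over the 4 of 34 ends measured, 1 of them, Smc1b, at 0.497%, against 1.89% over all measured genes, above 99.94% of 10000 random lists of the same size. Their gene bodies had a median of 85.8% at CpG (percentile 99.1) and 4.74% at CH (percentile 99.91), against 53.5% and 2.03% over all genes. Imprinted gene ends, methylated on 1 parental copy at some loci, had a median of 25.9% (percentile 99.4) over the 5 of 42 measured, and those of clustered protocadherins 17.5% over 3 of 58. Activity-dependent genes had the lowest gene body CpG level of the lists, a median of 8.42% (percentile 0).

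CH methylation was low in the bodies of clustered protocadherins, which overlap and share sites (median 1.00%), and in those of postsynaptic genes (1.18%, percentile 0.490). The methylation machinery had a median of 1.21% (percentile 5.32). Medians were 2.42% for pyramidal markers and 2.43% for interneuron markers (percentiles 72.5 and 71.5). Single genes stood far above their lists: the body of Foxp2, a transcription factor gene of deep layers, had 29.6% ± 1.37 CH methylation (SD over 8 libraries) at 132 sites, and that of Homer2, a postsynaptic scaffold gene, had 21.3% ± 0.791 in Control and 22.9% ± 1.29 in PFC DKO. Among the CH sites shared by the 8 libraries, 809 stood over 50% in every library, at 98.2% in Control and 97.4% in PFC DKO. Whether such sites set the levels of Foxp2 and Homer2 was not tested.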
